A study of Mus musculus with 6 samples.

How the data were processed

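RNA from sorted GFP-negative and GFP-positive DN4 thymocytes was depleted of ribosomal RNA before library preparation, per the labels' protocols. The submitters' processing notes name TopHat2, Cuffdiff and the mouse build mm10, with no versions; the settings and the annotation release are not given in the sources used here. The authors deposited FPKM values (fragments scaled to gene length and library size) per library and per group from a Cuffdiff run over 6 libraries and from another over 4, which left out library 1 of each group. Per the file headers, each deposited run also holds a test statistic, a score with no fixed range, and a p-value and q-value per gene. Log2 fold changes of the authors' group values were deposited as well, and in 1866 genes of the 6-library run and 1780 of the 4-library run the cell held a spreadsheet error where the GFP-positive group value was 0. These were read as minus infinity. In each run 27 gene symbols had been turned into dates and were replaced by GENCODE names. The third deposited table is a note on Gata3 that sets core reports, read counts and the deposited values side by side.

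Each run listed 41386 genes. Gene identifiers were matched to GENCODE M21 for position, biotype, length and GC content, which found 97.5% of them. FPKM scales with gene length, so that very short RNAs reach up to 18472500 FPKM and sums of FPKM say little about depth. In the 6-library run 24 genes carried the authors' status HIDATA, of which 23 were listed at 0 in every library, and these 24 were left out of the tests. Values of 0 in the tables can be failed estimates. Whether reads were assigned by strand is not given in the sources used here, so genes that overlap on opposite strands cannot be told apart.

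GFP-positive was compared with GFP-negative cells, 3 libraries against 3, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust) on log2(FPKM + 0.5), in genes with a mean FPKM of at least 1. Fold changes are on this log2(FPKM + 0.5) scale, which understates the change of low genes. P-values were adjusted by Benjamini and Hochberg's method, with a threshold of 0.05. A count test was not used, since FPKM are not counts. For Gata3 a two-sided exact permutation test was run with SciPy 1.17.1. Gene lists, 23 in number, were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and 20 lists with at least 3 tested genes were adjusted together. The 3 lists that passed with the preset correlation passed in 0 cases with the estimated one. Also planned and run was fry, which asks whether the genes of a list changed, without setting them against other genes. Its adjusted p was 0.000722 for the double-positive list and 0.0125 for each of the proliferation, growth and gamma-delta lists. It was also 0.000789 for the beta selection list, whose genes went both ways, and 0.346 for the TCR constant regions. Where 54.2% of all genes passed, fry says little about a list in particular. The lists, the tests, the rule for named genes and most of the alternatives were fixed before the data were examined.

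The rule named Gata3 and the genes of the third deposited table. In each list it named up to 4 genes past the threshold per direction, by size of the log2 fold change. Where none passed, it named the 2 with the highest mean FPKM as values. Also named, per direction and among genes past the threshold, were the 10 largest changes with at least 1 FPKM in both groups. Of those with at least 1 FPKM in a single group, the 5 largest per direction past the threshold were named. Not every gene that the rule names is given in the text.

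The procedure was tested on simulated data with the 11465 genes and 3 against 3 libraries, in 5 simulations with 200 changed genes each. It recovered 14.9% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 89.7% of those changed 4-fold, and 4.4% of its calls were false. Of 50 unchanged lists, 2 had a camera p under 0.05. Far fewer genes changed in the simulations than the 54.2% called in the data, so recovery in the data may differ. Genes were drawn independently, so the rates of false calls and lists need not hold for genes that vary together.

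Relative depth was read from genes below 0.3 FPKM with at least 1500 bp of exons, as the commonest ratio to GFP-negative library 1. Absolute depth stays unknown, so no counting intervals are given. Alternatives were pseudocounts of 0.1 and 1, no filter, a minimum mean FPKM of 5, quantile normalization, upper quartile scaling, limma without trend and robust, a replicate block and each library left out. Added after seeing the data were fits of genes the authors tested only, of protein-coding genes only, of the 4-library table and of the same 4 libraries in the 6-library table.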

Results

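Thymocytes at the DN4 stage were sorted by GFP from adult C57BL/6 mice carrying a Gata3 GFP reporter allele over a wild-type allele, and rRNA-depleted total RNA was sequenced. DN4 cells are the last of the double-negative thymocytes, which lack the coreceptors CD4 and CD8 at their surface. They have passed beta selection, the checkpoint for a productively rearranged T cell receptor (TCR) beta chain, and lie just before the double-positive stage, at which both coreceptors appear and the TCR alpha locus rearranges. The series held 2 groups, GFP-negative and GFP-positive cells, with 3 libraries each. The sort asks how cells without and with GFP from the Gata3 reporter allele differ, in a study concerned with GATA3 dosage and the control of TCR beta rearrangement.

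Expression was deposited as FPKM, and the total number of reads per library was not given in the sources used here. The steps between the lowest values gave relative depths of 0.865 to 1.28 times that of GFP-negative library 1, and the ratio of the Gata3 count to its FPKM gave 0.878 to 1.23. Both read the factor by which fragments were scaled to FPKM, so they are not independent measures of depth. Of the low genes, 12.2% to 26.4% lay at the commonest ratio. Between 10793 and 11632 genes reached an FPKM of 1 in a library. Across genes, Pearson correlations of log2 FPKM ran from 0.865 to 0.907 within GFP-negative cells and from 0.910 to 0.934 within GFP-positive cells, and the largest between groups was 0.852. The first principal component held 52.8% of the variance and separated the groups, with GFP-negative libraries at -73.6, -49.4 and -34.8 and GFP-positive libraries between 51.2 and 54.9. The second component, with 15.5%, set library 1 of both groups (38.5 and 38.0) apart from the other libraries (-42.0 to -7.85). Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

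Gata3, the zinc finger transcription factor required for T cell development whose reporter defined the sort, was 2.82-fold higher in GFP-positive cells. Its level was 22.5 ± 1.77 FPKM in GFP-negative and 63.3 ± 0.801 FPKM in GFP-positive cells (SD, n = 3 each), and the lowest GFP-positive library (62.7) lay above the highest GFP-negative library (24.3). The log2 fold change was 1.48 with a standard error of 0.11 (limma, adjusted p = 2.26e-05). A two-sided exact permutation test gave p = 0.10, the smallest that 3 against 3 allows. Gata3 (ENSMUSG00000015619) lies on the minus strand of chromosome 2, positions 9857078 to 9890034 of mm10, and the gene-level values do not separate the reporter allele from the wild-type allele. The authors' deposited table of 6 libraries gave it a q of 0.00019, and the authors' deposited table of 4 libraries a q of 0.00034.

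The same gene was the subject of the third deposited table, which set several sets of Gata3 values side by side. Reads counted per library were 450, 646 and 511 in GFP-negative cells and 1221, 1192 and 1501 in GFP-positive cells, a 2.44-fold difference of the means (exact permutation p = 0.10, two-sided, n = 3 each). An original report of a sequencing core gave 0.461, 5.68 and 5.44 FPKM in GFP-negative libraries 1 to 3 and 0.859, 15.4 and 14.3 FPKM in GFP-positive libraries 1 to 3. An updated report without library 1 of each group gave 0.471 and 5.81 FPKM in GFP-negative libraries 2 and 3, and 0.823 and 15.2 FPKM in GFP-positive libraries 2 and 3. Values from different reports were normalised separately and are compared only within a report.

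**Figure D1:**
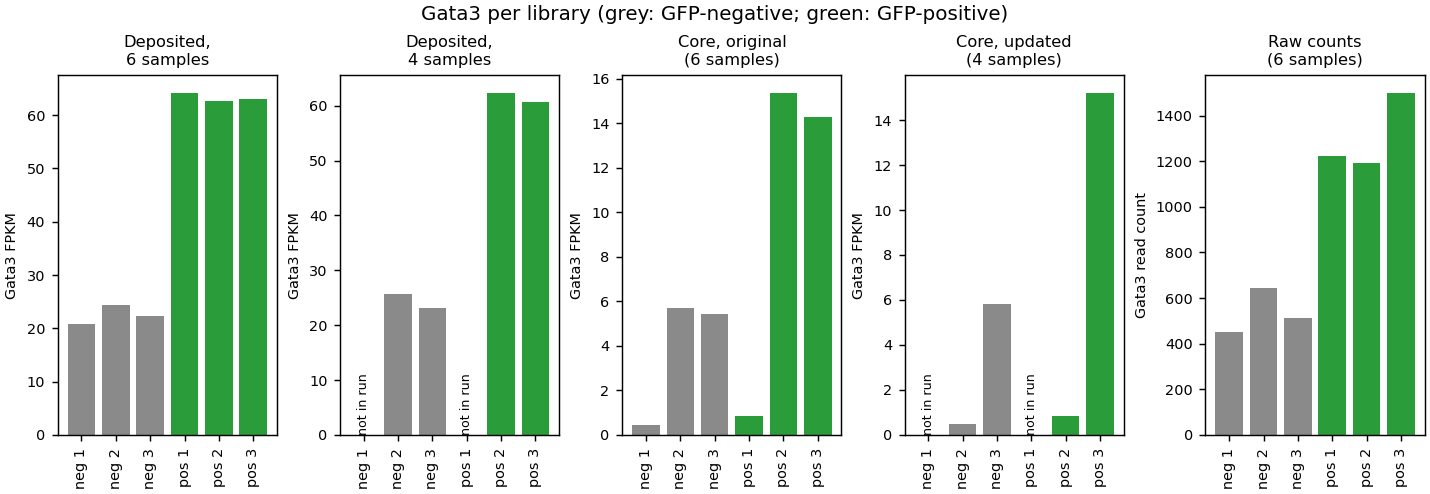
Gata3 in each library (bars; grey, GFP-negative; green, GFP-positive) as FPKM in the deposited runs of 6 and 4 libraries, as FPKM in the original and updated reports of the core, and as read counts, each panel with its own axis from 0. GFP-positive libraries lie at 62.7 to 64.2 FPKM in the 6-library table, while the first library of each group in both core reports lies below 1 FPKM.

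Most tested genes of the double-positive stage list were higher in GFP-negative cells, and most of the proliferation and growth lists in GFP-positive cells, although none of these lists passed with an estimated correlation (camera, adjusted p = 0.693). Cd4, the coreceptor of helper T cells, fell from 230 ± 34.8 FPKM in GFP-negative to 7.73 ± 2.21 FPKM in GFP-positive cells (SD, n = 3 each), a log2 fold change of -4.83 ± 0.19 (SE; limma, adjusted p = 3.02e-06). Rag1, a recombinase subunit of the V(D)J list, whose genes went both ways, fell from 1103 ± 235 to 120 ± 1.47 FPKM (log2 fold change -3.17 ± 0.16, adjusted p = 5.75e-06). Myc, a transcription factor that drives growth, rose from 27.1 ± 9.95 to 99.1 ± 9.62 FPKM (log2 fold change 1.91 ± 0.23, adjusted p = 0.000366). Tcrg-C1, a constant region gene of the TCR gamma chain, rose from 8.55 ± 3.69 to 38.6 ± 2.12 FPKM (log2 fold change 2.18 ± 0.24, adjusted p = 0.000267).

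Of 11465 genes tested, 6216 (54.2%) passed an adjusted p of 0.05, 2797 of them higher and 3419 lower in GFP-positive cells. At least a 2-fold difference was seen for 985 of the higher and 1483 of the lower genes, and at least an 8-fold difference for 1 and 93. The values of the groups did not overlap for 7315 genes (63.8%), where chance gives 10%. Quantile normalization, which moved the median log2 fold change of all genes up by 0.13 from -0.08, turned the split to 3494 higher and 2846 lower genes, so the balance of directions rests on the scaling.

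**Figure D2:**
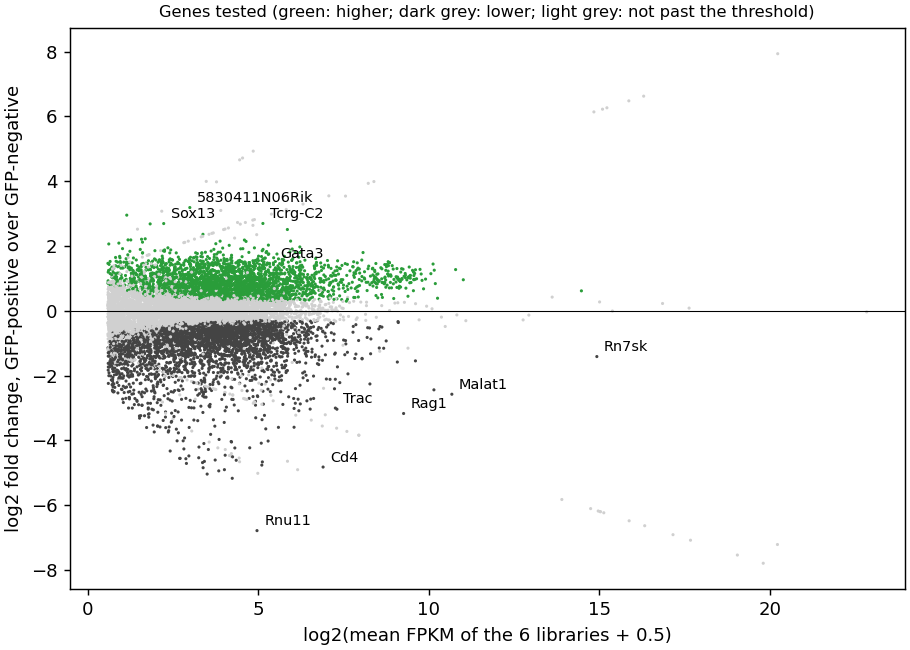
Log2 fold change (GFP-positive over GFP-negative) against log2 of the mean FPKM plus 0.5 for the 11465 genes tested, each a point (green, higher; dark grey, lower; light grey, not past the threshold). Lower genes reach further from 0 than higher genes, with 93 against 1 at 8-fold or more.

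The largest decreases among genes past the threshold with at least 1 FPKM in both groups were dominated by Cd4 and by variable segments of the TCR alpha locus. Trav6-7-dv9 fell from 65.8 ± 33.0 to 1.82 ± 0.645 FPKM (SD, n = 3 each; log2 fold change -4.77), Trav14-1 had a log2 fold change of -4.67 (-5.28 without GFP-positive library 1) and Trav14-2 one of -4.23. Variable segments are near copies of each other, so the counting of reads between them is uncertain. Als2cl (log2 fold change -4.24), Inadl, a scaffold protein of cell polarity (-4.09), and Nav2 (-4.05) fell as well. Slc15a2, a peptide transporter (-4.62), Trav14n-3 (-4.61) and Gm16042 (-4.51) completed the 10. These last calls were lost under some alternatives while the folds stayed large. The authors' deposited table of 6 libraries did not call Slc15a2 and Gm16042 (q of 0.0828 and 0.240), and called Trav14n-3 (q of 0.0183). Slc15a2 stood at 0.227, 0 and 8.55 FPKM in GFP-positive libraries 1 to 3; it lost its call when any library except GFP-positive library 3 was left out (log2 fold change -3.83 to -4.84; -5.92 without that library), with a pseudocount of 0.1 (-5.78), with the replicate block (-4.62) and in both fits of 4 libraries (-3.95 and -3.99), at adjusted p up to 0.272. Gm16042 stood at 6.98, 0.328 and 0.0770 FPKM in GFP-positive libraries 1 to 3 and lost its call when any library except GFP-positive library 1 was left out (-3.81 to -4.55, adjusted p up to 0.0950; -5.66 without that library), and Trav14n-3 lost its call without GFP-positive library 2 (-4.13, adjusted p = 0.0538; -5.57 without GFP-positive library 1).

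Among genes past the threshold with less than 1 FPKM in GFP-positive cells, Rnu11, an RNA of the minor spliceosome, stood at 61.2 ± 36.3 FPKM in GFP-negative cells (SD, n = 3). It was listed at 0 in each GFP-positive library, and such a 0 can be a failed estimate. Trav13-1, Trav7d-5, BC028471 and Gm15340 followed with log2 fold changes of -5.17, -5.04, -4.94 and -4.91. The authors' deposited table of 6 libraries did not call Rnu11, Trav13-1 and Trav7d-5 (q of 0.218, 0.349 and 0.204), and called BC028471 and Gm15340 (q of 0.00019 and 0.000529).

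The largest increases were ranked among genes past the threshold with at least 1 FPKM in both groups. They were 5830411N06Rik, a scavenger receptor gene related to Cd163l1 (1.14 ± 0.695 to 13.7 ± 2.05 FPKM, SD, n = 3 each, log2 fold change 3.19) and genes of the TCR gamma locus. Tcrg-C2 had a log2 fold change of 2.70, Trgv2 of 2.51, Tcrg-C1 of 2.18 and Tcrg-V1 of 2.07. GFP-negative library 3 stood apart for Tcrg-C2, at 20.4 FPKM against 5.56 and 5.49 in libraries 1 and 2, and without it the log2 fold change of Tcrg-C2 was 3.29. Gpr25, an orphan receptor (2.36), Gzma, a cytotoxic granule protease (2.15), Gfra1, a receptor of glial cell-derived factors (2.15), Plac8 (2.14) and Ybx3, a nucleic acid-binding protein (2.03), completed the 10. Among genes past the threshold with less than 1 FPKM in GFP-negative cells, Sox13, a transcription factor of gamma-delta T cells, rose from 0.801 ± 0.544 to 7.54 ± 1.16 FPKM (log2 fold change 2.69, limma adjusted p = 0.00016). Olfr524, Rpp14 and Ifitm2 had log2 fold changes of 2.68, 2.22 and 2.21 from levels below 1 FPKM. Gm15791 was listed at 0 in each GFP-negative library, where 0 can be a failed estimate, and at 3.41 ± 0.644 FPKM in GFP-positive cells. The authors' deposited table of 6 libraries did not call Gm15791 and Rpp14 (q of 0.209 and 0.198), and called Sox13, Olfr524 and Ifitm2 (q of 0.00019, 0.0132 and 0.0103).

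**Figure D3:**
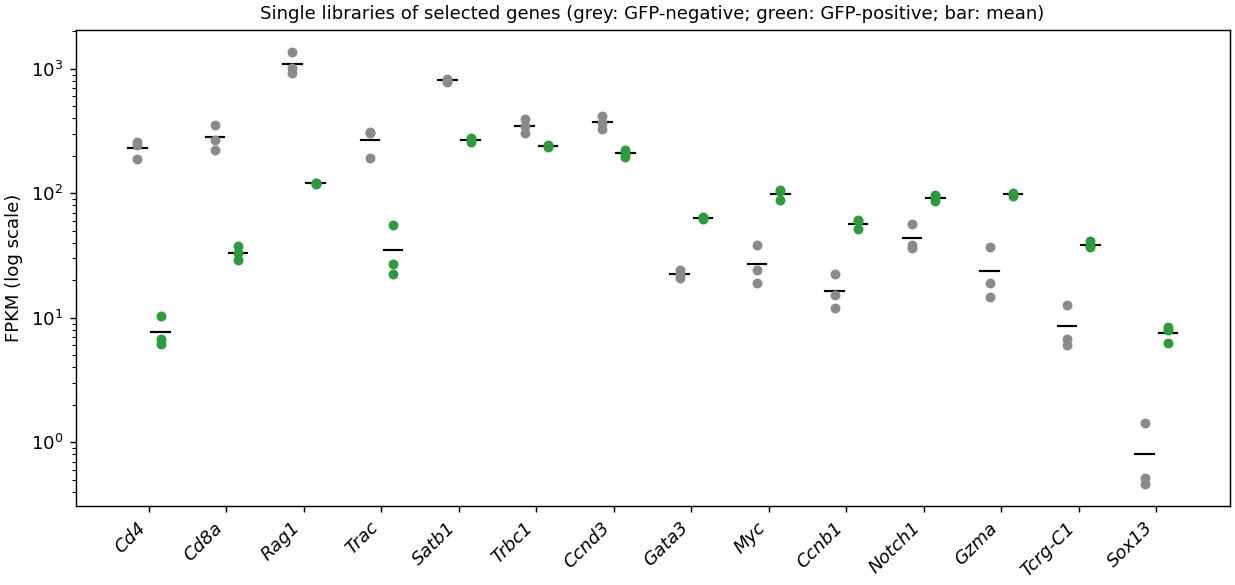
FPKM of selected named genes in each of the 6 libraries (points; log axis; grey, GFP-negative; green, GFP-positive; bar, mean). Cd4 falls from a mean of 230 to 7.73 FPKM and Sox13 rises from 0.801 to 7.54 FPKM, and the libraries of the groups do not overlap for any gene shown.

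Gene lists fixed before the data were examined were then compared. Of 23 genes of the double-positive stage tested, 20 fell in GFP-positive cells and 0 rose (22 fell adjusted over the list alone), with a median log2 fold change of -1.59. Cd8a, a chain of the CD8 coreceptor, fell from 281 ± 68.6 to 33.3 ± 4.12 FPKM (SD, n = 3 each; log2 fold change -3.04), Ccr9, a chemokine receptor of thymocytes, from 163 ± 35.6 to 19.3 ± 3.07 FPKM (-3.04), and Slc7a11, a cystine transporter, from 19.5 ± 1.62 to 0.664 ± 0.0683 FPKM (-4.10). The list passed camera with a preset correlation (adjusted p = 2.11e-08) and did not with the correlation estimated from these libraries (adjusted p = 0.693 with an estimated correlation). The preset correlation also passed 2 to 8 lists in the 9 splits of the libraries that mixed the groups. Such splits keep part of the group difference and differences between single libraries, so these passes are not a rate of false calls. Since 0 lists passed with the estimated correlation, the list p-values are weak evidence. The counts of members make no allowance for genes that vary together either. They stand beside 2797 higher and 3419 lower genes among all 11465 tested.

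All but 1 of the 36 proliferation genes rose in GFP-positive cells, 35 in all and also 35 adjusted over the list alone, with a median log2 fold change of 1.48. Ube2c, a ubiquitin-conjugating enzyme of mitosis, rose from 30.2 ± 8.33 to 117 ± 8.37 FPKM (SD, n = 3 each; log2 fold change 1.97), Plk1, a mitotic kinase, from 14.6 ± 3.94 to 54.7 ± 4.93 FPKM (1.89), and Ccnb1, the mitotic cyclin, from 16.6 ± 5.27 to 57.2 ± 4.89 FPKM (1.80). The D-type cyclins parted: Ccnd2 had a log2 fold change of 1.79, while Ccnd3, needed for the expansion after beta selection, fell from 373 ± 46.1 to 210 ± 14.4 FPKM (-0.82). In GFP-negative library 3 the mean log2 level of the list was 5.10 against 4.30 and 4.51 in libraries 1 and 2, and without it the median log2 fold change was 1.74. The list passed camera (adjusted p = 1.1e-12; adjusted p = 0.693 with an estimated correlation).

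Of 19 genes of Myc and growth metabolism, 16 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 1.05. Slc7a5, a large amino acid transporter, had a log2 fold change of 1.91, Tpi1, a glycolytic enzyme, 1.61, and Npm1, a nucleolar protein, 1.49. Slc1a5, a glutamine transporter, had the opposite sign (-0.39), a call lost under 8 alternatives (adjusted p up to 0.171). The list passed camera (adjusted p = 1.02e-05; adjusted p = 0.693 with an estimated correlation).

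Of 10 gamma-delta T cell genes, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with a median of 1.96. Of the 8, 5 lay below 1 FPKM in GFP-negative cells, and 5 further genes of the list were below the minimum for testing (highest group mean 0.235 FPKM). Cd163l1, a scavenger receptor found on gamma-delta T cells, rose from 0.368 ± 0.229 to 3.41 ± 0.723 FPKM (SD, n = 3 each; log2 fold change 2.19). Sox4, also expressed in other thymocytes, fell with a log2 fold change of -0.81. The list as a whole just missed the threshold (camera, adjusted p = 0.05005; adjusted p = 0.693 with an estimated correlation).

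The 6 TCR constant region genes tested split by locus, 3 higher and 3 lower (3 and 3 adjusted over the list alone; median 0.84, camera adjusted p = 0.883). Trac, the TCR alpha constant region, fell from 270 ± 68.3 to 35.03 ± 17.8 FPKM (SD, n = 3 each; log2 fold change -3.004), and Trbc1, of the TCR beta chain, from 348 ± 44.7 to 241 ± 4.46 FPKM (-0.52). Trbc2 stood at 610 ± 58.8 and 482 ± 24.0 FPKM (-0.33), a call lost under 10 alternatives (adjusted p up to 0.159). Tcrg-C4 had a log2 fold change of 2.02 (2.51 without GFP-negative library 3, which stood at 12.8 FPKM against 4.36 and 4.33 in libraries 1 and 2), and its call and that of Tcrg-C2 were lost in the fits without library 1 of both groups (adjusted p up to 0.0924 and 0.116), at log2 fold changes of 1.75 and 1.70 for Tcrg-C4 and of 2.47 and 2.45 for Tcrg-C2.

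Genes of V(D)J recombination went both ways, with 4 of 18 higher and 7 lower (4 and 7 adjusted over the list alone; median -0.03, camera adjusted p = 0.934). Rag2, the partner of Rag1, fell from 73.2 ± 18.8 to 19.9 ± 1.93 FPKM (SD, n = 3 each; log2 fold change -1.83), and Dclre1c, the hairpin-opening nuclease Artemis, had a log2 fold change of -2.05. H2afx, the histone variant that marks DNA breaks (1.51), Hmgb2, a DNA-bending protein (1.23), Xrcc5, the Ku80 end-binding subunit (1.13), and Atm, the kinase that responds to breaks (0.73), rose.

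Of 20 genes of beta selection, the pre-TCR and Notch signalling, 7 rose and 8 fell (8 and 9 adjusted over the list alone; median 0.06, a mean just below 0 and a camera test in the direction of a decrease, adjusted p = 0.934). Notch1, the receptor that specifies T cells, rose from 43.8 ± 11.3 to 91.6 ± 4.84 FPKM (SD, n = 3 each; log2 fold change 1.09), Hes1, a Notch target, had a log2 fold change of 1.84 and Il7r, a cytokine receptor chain, one of 1.84. Cd27, a costimulatory receptor (-2.15), Themis, a regulator of TCR signalling (-1.95), Cd247, the CD3 zeta chain (-1.25), and Lck, the kinase that starts TCR signalling (-1.16), fell.

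T lineage transcription factors fell more often than they rose, 13 against 4 of 24 (13 and 4 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.159). Satb1, a chromatin organiser, fell from 807 ± 24.2 to 269 ± 9.39 FPKM (SD, n = 3 each; log2 fold change -1.58), Myb from 216 ± 28.0 to 84.5 ± 3.96 FPKM (-1.34), and Zfpm1, the GATA cofactor FOG1, rose from 9.51 ± 1.57 to 19.9 ± 2.62 FPKM (1.03). Of 6 Th2 and GATA3-associated genes tested, 2 rose and 3 fell (2 and 3 adjusted over the list alone; median -0.69, camera adjusted p = 0.719). Il4ra, the interleukin 4 receptor chain, fell from 26.5 ± 6.41 to 1.25 ± 0.603 FPKM (log2 fold change -3.97), while Il17rb had a log2 fold change of 0.91, a call lost in the 4-library table (adjusted p = 0.0531, lowest over alternatives 0.00145).

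Of 15 genes of p53 and apoptosis, 2 rose and 8 fell (2 and 8 adjusted over the list alone; median -1.02, camera adjusted p = 0.131). Fas, a death receptor, had a log2 fold change of -2.94, Trp53inp1 of -2.41, Bbc3, which encodes PUMA, of -2.17, and Bcl2l1, which encodes the survival protein of double-positive cells Bcl-xL, of -2.01, while Trp53 itself had one of 0.74. Interferon response genes had 1 higher and 5 lower of 13 (1 and 5 adjusted over the list alone; median -0.53, camera adjusted p = 0.719), with Igtp at -1.83 and Bst2 at 1.02. Immediate early and heat shock genes had 3 higher and 4 lower of 16 (3 and 4 adjusted over the list alone; median -0.76, camera adjusted p = 0.719), with Zfp36 at -2.48 and Hsph1 at 1.19. Fos, Jun and Dusp1, chosen after their values were seen, had log2 fold changes of -1.95, -1.77 and -1.79 that missed the threshold (adjusted p of 0.0739, 0.0958 and 0.0796) and were highest in library 1 of each group: Fos at 43.3, 15.1 and 10.8 FPKM in GFP-negative and 9.68, 3.46 and 2.81 in GFP-positive libraries 1 to 3, Jun at 114, 29.7 and 22.2 in GFP-negative libraries 1 to 3 and 17.0 in GFP-positive library 1, and Dusp1 at 87.8, 27.9 and 21.4 in GFP-negative and 17.4, 6.89 and 9.48 in GFP-positive libraries 1 to 3.

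Markers of other cells were mostly low. Mature T cell genes had 4 higher and 3 lower of 13 (5 and 4 adjusted over the list alone; median 0.45, camera adjusted p = 0.719), with Cd52 at a log2 fold change of -3.09, Gimap6 at -2.50 and Ctla4 at 1.33. Among NK and innate lymphoid markers 1 of 4 rose, Gzma (median 0.74, camera adjusted p = 0.58). The other 3, chosen after their values were seen, were highest in library 1 of each group: Id2 at 8.28 and 9.20 FPKM in GFP-negative and GFP-positive library 1 against 2.01 to 3.57 in the other libraries, Il2rb at 3.15 and 6.32 against 0.158 to 0.863, and Nkg7 at 2.95 and 5.28 against 0.199 to 1.67. The B cell list had 1 higher and 1 lower of 4 (median -0.10, camera adjusted p = 0.97), with Cd79b, a B cell receptor chain, at -1.41. Dendritic cell markers had 2 higher and 1 lower of 5 (median 0.27, mean -0.05, camera in the direction of an increase, adjusted p = 0.719), with Irf8 at 1.35 and Ccr9 at -3.04. Thymic stroma had 0 higher and 1 lower of 4 (median 0.24, camera adjusted p = 0.934), namely Pecam1 at -0.74. Adjusted over the list alone, these 4 lists gave the same counts. The early progenitor list had 0 of 3 past the threshold (also 0 adjusted over the list alone; camera adjusted p = 0.934), with Cd44 at 3.37 ± 1.06 and 1.57 ± 1.18 FPKM (SD, n = 3 each). Myeloid cells were represented only by Cd68 (2.07 ± 0.862 and 1.81 ± 0.559 FPKM, limma adjusted p = 0.731), and of 2 erythroid genes Car2 had a log2 fold change of -2.17.

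**Figure D4:**
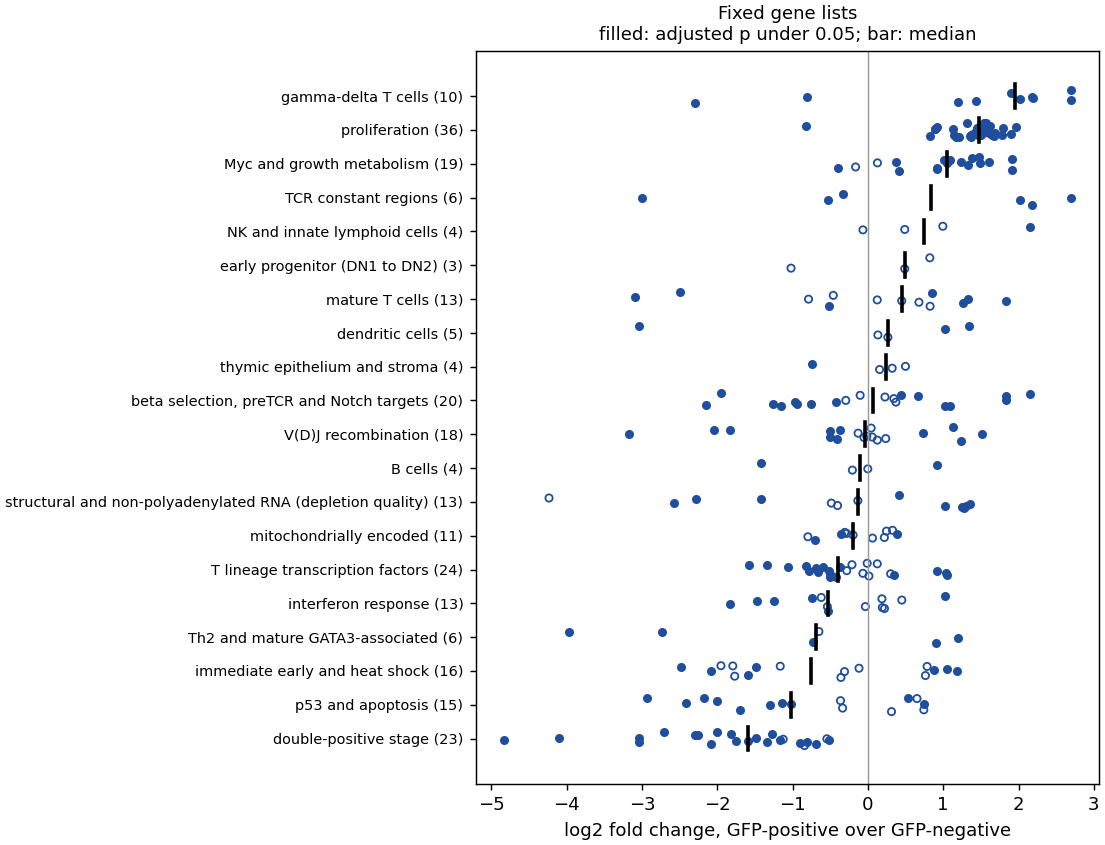
Log2 fold change (GFP-positive over GFP-negative) of each tested member of 20 fixed lists (points; filled, adjusted p under 0.05; open, not past it; black bar, list median; number of genes in parentheses). The double-positive list has a median of -1.59 and the proliferation list one of 1.48.

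Measures of the RNA fraction differed too. Of 13 structural and non-polyadenylated RNAs, 6 rose and 3 fell (6 and 3 adjusted over the list alone; median -0.13 and a camera test in the direction of an increase, adjusted p = 0.719). Histone transcripts, which lack a poly(A) tail and are made in S phase, rose, with Hist1h3c at 1.36 and Hist1h1b at 1.30. The nuclear RNAs Malat1 (2802 ± 781 to 459 ± 42.0 FPKM, SD, n = 3 each; log2 fold change -2.58) and Neat1 (-2.28) fell. Rn7sk stood at 45217 ± 8758 and 16904 ± 2847 FPKM (-1.41), and its sign turned under quantile normalization (0.18). Mitochondrially encoded genes had 1 higher and 2 lower of 11 (0 and 0 adjusted over the list alone; median -0.20, camera adjusted p = 0.934).

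The authors' deposited tables held the same comparison with all 6 libraries and with libraries 2 and 3 of each group. In the authors' deposited table of 6 libraries 5732 genes with at least 1 FPKM in either group had a q under 0.05, 2719 higher and 3013 lower in GFP-positive cells. In the authors' deposited table of 4 libraries 4074 did, 1899 higher and 2175 lower. Of these, 3996 were called in both with the same direction and 0 with opposite directions, 1736 only with 6 libraries and 78 only with 4. Log2 fold changes of the authors' deposited tables had a Pearson correlation of 0.978 across 11400 genes, which share libraries and are not independent replicates. Of the 6216 genes called by limma, 5217 were also called in the authors' deposited table of 6 libraries, all 5217 in the same direction, and 394 of the genes limma tested were called in the authors' deposited table only. The 999 genes called by limma only included the list genes Zfpm1, Slc7a5, Irf8, Car2 and Rag2. Their q in the authors' deposited table of 6 libraries was 0.612, 0.332, 0.175, 0.0852 and 0.0617.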

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

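The value below was singled out by a comparison chosen after the data were seen, and no explanation of it was tested. mt-Rnr1, the mitochondrial 12S ribosomal RNA, carried the authors' status HIDATA and stood outside the tests. It was listed at 48429 ± 992 FPKM in GFP-positive cells (SD, n = 3) and at 0 in each GFP-negative library. A value of 0 for so abundant an RNA can be a failed estimate, and the other 23 genes with this status were listed at 0 in all 6 libraries.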

How the results depend on the processing

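The fits limited to genes the authors tested or to protein-coding genes, of the 4-library table and of the same 4 libraries in the 6-library table were chosen after the data were seen. The number of genes past the threshold ran from 4815 to 6424 over 18 alternatives against 6216, and from 5052 to 6130 with 1 library left out. Of the 6216 genes, 5531 kept their call under quantile normalization, 1 was called with the opposite sign, and 4665 kept it in the 4-library table. Without library 1 of both groups 4815 genes were called in the 4-library table and 5101 in the 6-library table. Gata3 kept its direction and call throughout, with log2 fold changes of 1.42 to 1.53 when a library was left out. With the replicate block 6390 genes were called. Deviations of libraries with the same number correlated at 0.09, -0.02 and 0.06, so the numbers were not taken as pairs. In these deviations library 1 of each group correlated best with library 1 of the other group, and it lay beside it on the second component, while neither library 2 matched by number and library 3 did so from the GFP-positive side only.

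Of 120 further named genes, 98 kept direction and side of the threshold under each alternative that tested them, 20 lost the call under at least 1, and Cd44 gained it under 7. Some genes were not tested under every alternative. Rn7sk reversed under quantile normalization (0.18); the cause was not tested. With an estimated correlation 0 lists passed, which ended the calls of the double-positive (median -1.59), proliferation (1.48) and growth (1.05) lists. At a minimum mean FPKM of 5, with fewer genes tested, 5 lists passed, among them T lineage transcription factors (-0.50) and p53 and apoptosis (-1.14). Quantile normalization also passed the transcription factors (-0.44). The gamma-delta list passed with a pseudocount of 1 (1.62), with no filter (1.31), with no trend or robust (1.96), for genes the authors tested (1.96) and without GFP-negative library 3 (2.18, leave-one-out range 1.81 to 2.18), and its adjusted p ran from 0.00894 to 0.788. The structural RNA list passed among protein-coding genes only (1.26), where it is left with histones. Apart from these named causes the cause was not tested.

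Count-based tests were not run because per-library FPKM were used, and the alternatives planned for group values alone did not apply. Genes shared between the authors' deposited tables numbered 2885 at q under 0.01 against 3996. Absolute depth is unknown, so what it limits was not tested. In simulations of 3 against 3 libraries with 200 changed genes each, 14.9% of 1.5-fold changes were recovered. Recovery may differ in the data, where 54.2% of genes passed.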

Other observations

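The gene families, the test against a 2-fold difference, the Cd4 level, the gamma-delta and other cell markers and the Gata3 reports were chosen as tests after results were seen. The correction for GC content and length, the comparison with TCR beta variable genes and the splits of the libraries were set before their results were seen.

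Further families were described by their shared gene names. All 73 ribosomal protein genes rose in GFP-positive cells, with a median log2 fold change of 0.97 and a summed level of 24063 ± 3718 against 47128 ± 2671 FPKM (SD, n = 3 each), although quantile normalization left 47 of them past the threshold with a median of 0.36. Replication-dependent histones had 50 of 52 higher (median 1.23; 6 of the 52 are also in the structural RNA list), proteasome subunits 33 of 37 (0.68), mitochondrial ribosomal proteins 63 of 76 (0.80), respiratory complex I subunits 35 of 44 (0.65) and chaperonin subunits 6 of 6 (0.97). Translation initiation factors had 31 higher and 4 lower of 52 (0.57), and tubulins 6 higher and 3 lower of 10 (camera adjusted p = 0.0898). Gimap genes, GTPases of lymphocyte survival, had 6 of 7 lower (median -1.41), and 97 of 263 zinc finger genes were lower against 15 higher (-0.31), or 73 against 26 under quantile normalization (-0.15). Each of these medians kept its sign under both scalings. With an estimated correlation no family passed (camera, adjusted p of 0.269 to 0.724 over 14 families).

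TCR variable genes parted by locus. Of 58 Tcra variable genes 53 were lower in GFP-positive cells, and their summed level was 600 ± 183 FPKM in GFP-negative and 72.0 ± 14.8 FPKM in GFP-positive cells (SD, n = 3 each). Of 21 Tcrb variable genes 17 were lower, with a summed level of 1456 ± 210 and 898 ± 54.1 FPKM. The 3 Tcrg variable genes had a median of 2.51, 2 of them past the threshold, and of 4 Tcrd variable genes 0 were higher and 1 lower, which became 1 and 0 under quantile normalization and 1 and 1 under upper quartile scaling.

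Double-positive stage genes were higher in GFP-negative cells, and a correction for GC content and gene length left their median at -1.52 against -1.59 before, which argues against that bias as the cause. Tcra variable genes had a median of -2.65 against -0.70 for Tcrb variable genes, a value consistent with more cells past Tcra rearrangement among GFP-negative cells. A minority of double-positive cells among cells otherwise like GFP-positive ones would keep other genes within 2-fold. Limma's test against 2-fold found 22 genes lower in GFP-negative cells beyond it, and 406 higher. The 22 are under the limit of 50 set for the test and so did not exclude such a mixture. P-values were adjusted over both directions together, so how many of the 22 are false is not known. That limit of 50 had no derivation, and a strict mixture allows no such gene. The 22 genes, with that reserve, and the proliferation median of 1.48 speak against a minority as the whole cause without settling it. Double-positive cells that passed the sort and double-negative cells that already transcribe these genes cannot be told apart, since both give a high Cd4 level (230 FPKM in GFP-negative and 7.73 in GFP-positive cells) and surface protein was not analysed here.

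TCR gamma constant genes were higher in GFP-positive cells, and a candidate explanation is a larger share of gamma-delta T cells there. Of 5 tested non-receptor markers of these cells that no other fixed list holds, 4 rose (Sox13, Etv5, Cd163l1 and Blk, some of them chosen after their values were seen) and Sox4, which other thymocytes express, fell. All 4 lay below 1 FPKM in GFP-negative cells and passed the minimum only by their level in GFP-positive cells, and 4 more markers lay below it in both groups (highest group mean 0.217 FPKM; with no filter the 3 not at 0 throughout had limma adjusted p of 0.216 or more), so the count decides nothing and this explanation stays open. Of the 4 Tcrd variable genes, of the TCR delta locus, 0 were higher and 1 lower in GFP-positive cells. Their summed level was 34.9 ± 2.74 FPKM in GFP-negative and 42.8 ± 6.27 FPKM in GFP-positive cells (SD, n = 3 each). These calls changed with the scaling, so they do not decide it either. Trdc, the TCR delta constant gene, was not matched in the deposited values and could not be read. Dilution of all other cell types alike in GFP-negative cells would raise their markers by about as much as the smallest TCR gamma constant gene (2.02), and 18 markers of B, myeloid, dendritic, NK and stromal cells had an upper quartile of 0.81, but 5 of them, such as Ccr9, are also in other lists, 9 lie under 5 FPKM in GFP-positive cells, and thymocytes may express the 4 left (Ighm stood at 143 and 144 FPKM), so dilution stays open too. Transcription of the gamma locus in cells not yet committed to a lineage also stays open and was not tested, and whether the sort removed gamma-delta T cells is not given in the sources used here.

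In the earlier reports of the core, Gata3 lay below 1 FPKM in some libraries. Their read counts were 77.8% to 134% of the mean of the other libraries of their group, which argues against a low Gata3 level in them. All 4 libraries listed first in their group and run lay below 1 FPKM and 0 of the others did, and GFP-negative library 2 stood at 5.68 beside 5.44 FPKM of library 3 within the original report and, listed first, at 0.471 beside 5.81 FPKM within the updated one, so the place in the run is a candidate cause. How the core computed these values was not tested.

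The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.1. For the number of genes, 1 of the 10 splits gave as many as the real one, itself (6216, highest other 4). Splits that mix the groups carry the group difference into the spread within each side, which removes calls. Their low counts therefore do not show what chance alone would give. For the number of lists passed by camera with a preset correlation, 9 of the 10 splits gave as many as the real one (3, highest other 8). Splits that mix the groups keep part of the group difference, so these list counts do not show what chance alone would give either.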
